A study of Homo sapiens with 10 samples.

How the data were processed

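Total RNA from H295R cells was hybridised, as biotin-labelled target, to Affymetrix human expression arrays of 2 types, here called array A and array B, which carry different sets of probe sets. H295R is a human adrenocortical carcinoma line that makes aldosterone, cortisol and adrenal androgens. There were 5 samples, all taken at 3 h: 2 controls, 1 treated with angiotensin II at 100 nM, 1 with potassium at 16 mM and 1 with forskolin at 10 µM. The same biological sample was put on both array types, so the 10 arrays hold 5 samples and an array B measurement is a technical repeat of array A, not a replicate. No label says that the 2 controls came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

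The deposited values are linear intensity (signal), with 1 value per probe set and array, made by the authors with GCOS 1.2, per the submitters' processing notes. The algorithm settings and the detection calls are not given in the sources used here. The deposited values had already been scaled per array. After leaving out the highest and lowest 2% of probe sets, the mean signal was 499.9 on each array A and 499.96 on each array B. The rule fixed in advance was to keep the values as deposited if these means lay within 10% of each other, and they were kept. No count of molecules or depth lies behind a signal, and the number of arrays limits the precision. Of the value columns, 0 were left unused.

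The 68 control probe sets of each array type were left out, as were the probe sets in the lowest 40% by mean log2 signal over the 5 arrays of a type. This left 13329 of 22215 probe sets on array A (mean signal over 92.8) and 13546 of 22577 on array B (over 149), or 26875 in all. The test was limma (lmFit and eBayes with a trend on signal) on log2(signal + 16), two-sided, with Benjamini-Hochberg adjustment over the probe sets of 1 array type and an adjusted p threshold of 0.05. Array types were fitted separately and their counts of calls were added. Each fit held 4 groups in 5 samples, so the only residual degree of freedom came from the 2 controls. Each agent had 1 sample, which was assumed to vary like the controls. limma's prior degrees of freedom were 7.44 on array A and 7.67 on array B, and the median moderated SD was 0.147 and 0.300 on the log2 scale. Fold changes are on the log2(signal + 16) scale, which understates the change of dim probe sets. An error given after ± is the standard error from limma for a log2 change and the SD of the 2 controls for a signal. The adjusted p-values printed are those of limma.

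Probe sets were named through the platform annotation, with symbols updated through the RefSeq gene table, which served for names only. On array A, 19071 probe sets had 1 gene symbol, 1043 had several and 2169 had none. On array B these numbers were 15432, 554 and 6659. Probe sets with several symbols were tested but not named, and for this reason CYP21A2, whose probe set is shared with its pseudogene, is not reported. CYP11B1 and CYP11B2 are near-identical copies, so their probe sets can cross-hybridise and their values are uncertain. In all, 12369 genes had a named probe set that was tested, 7836 read on array A and 4533 on array B.

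The following choices were made before the data were examined: the groups, the tests, the filter, the alternatives other than the 3 identified here as added, the gene lists and the rule for naming genes. Each gene was read from 1 probe set, preferring in order one that passed the filter, one without the suffix that marks shared probes, array A over array B, and the highest mean signal. For each agent, the 15 largest rises and 10 largest falls were named among the genes with an adjusted p under 0.05 and a change of at least 1.5-fold in the same direction against each of the 2 controls. For each difference between 2 agents, the 5 largest in each direction were named by the same rule. STAR, CYP11B1, CYP11B2, CYP17A1, HSD3B2, CYP21A2, CYP11A1, NR4A1, NR4A2, NR4A3, MC2R and AGTR1 were to be named in any case. Members of a gene list could be named as examples, those with the smallest adjusted p first. XIST and Y-linked genes were left out.

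The 17 gene lists covered steroidogenesis, cholesterol synthesis and uptake, immediate early genes, feedback regulators of MAP kinase signalling, targets of cyclic AMP and CREB, calcium and potassium handling, the activin, inhibin, BMP and TGF-beta group, growth factors and cytokines, the circadian clock, the cell cycle, unfolded protein and amino acid stress, heat shock, glycolysis and hypoxia, and markers of adrenal medulla, endothelium, fibroblasts and immune cells. The immediate early list and the cyclic AMP list shared 7 tested genes. For each list and agent, the genes that rose or fell were counted with the adjustment over all probe sets and also adjusted over the list alone. The median log2 change was placed among the medians of 10000 random lists of the same size, matched on array type and on 20 bins of signal. This percentile describes these samples and is not a test across samples.

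Agents were also compared with each other in the same fits. The 3 agent samples together were compared with the 2 controls in a fit of 2 groups. All agents share the 2 controls. Overlaps of probe sets and correlations between agents are therefore given beside the values from 50 simulated sets of unchanged agents against the same controls. Overlaps are also given beside the number for independent lists, and overlaps of genes beside that number alone. Counts by size alone, of probe sets at least 2-fold from the control mean, are given beside the number with the 2 controls at least 2-fold apart. A difference between lone arrays is by itself wider than a difference from a mean of 2, so the counts against each control alone are the closer match.

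The alternatives were quantile normalization, centring on the array median, a pseudocount of 1 or 64 in place of 16, no filter, leaving out the lowest 60%, eBayes without the trend, robust eBayes, a minimum fold of 1.5 in the test, the mean of a gene's probe sets, and leaving out samples in turn. Array A alone, an overlap with a different control for each agent, and a fit with the prior degrees of freedom halved were chosen after seeing the data. Leaving out a control leaves no residual degree of freedom for the test of an agent, so only values without a test were recomputed in that way.

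The test was checked on simulated data with the spread and prior degrees of freedom of the real arrays, in 10 draws with 200 changed probe sets per agent. For angiotensin II, 63.2% of 2-fold changes and 96.4% of 4-fold changes were called among the 13329 probe sets of array A, against 20.6% and 52.8% among the 13546 of array B. The false share of calls in these draws was 19.4% on array A and 18.4% on array B for angiotensin II, 19.1% and 19.1% for potassium, and 20.0% and 19.0% for forskolin, above the 5% that the threshold names. With 1 residual degree of freedom the prior degrees of freedom are poorly known. The simulated value of 7.44 for array A was estimated at 7.95 to 35.6, and 7.67 for array B at 5.75 to 40.2. On array A even the lowest estimate lay above the simulated value. The fitted prior degrees of freedom may therefore be too high and the p-values too small. In a separate simulation of agents without any effect, a mean of 5.18 probe sets was called for angiotensin II, 5.82 for potassium and 4.16 for forskolin. It had 50 draws, with at most 19, 20 and 18 calls. Its noise came from each probe set's moderated SD, which varies less than the variances drawn in the first simulation. It can therefore understate false calls. Over the 10 draws of the first simulation together, 341 unchanged array A probe sets were called for potassium. Per draw this is more than the 27 array A probe sets that potassium changed in the real data. Each draw also held 200 changed probe sets, which loosens the adjusted threshold, so the 2 numbers are not fully alike. Of 200 simulated lists of 20 genes without an added shift, 6.5% fell outside the central 95% of random lists, and of lists shifted by 0.50 on the log2 scale 99% did. The software was R 4.3.3, limma 3.58.1, and Python 3.11.15 with matplotlib 3.10.9 for the plots.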

Results

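Expression was measured in H295R human adrenocortical cells after 3 h with 1 of 3 agents that regulate adrenal steroid secretion. Angiotensin II (100 nM) acts on these cells through the angiotensin type 1 receptor and calcium, added potassium (16 mM) depolarises the membrane, and forskolin (10 µM) activates adenylyl cyclase and so raises cyclic AMP. The comparisons ask which transcripts each agent changed, how the agents differed and what they shared. There were 2 control samples and 1 sample per agent, each on array A and array B. The controls correlated across probe sets with r = 0.984 on array A and 0.921 on array B, where probe sets are not independent replicates. The SD of their log2 difference was 0.293 and 0.586, and 118 and 1151 probe sets lay at least 2-fold apart between them. Because each agent had 1 sample, no agent value has a replicate of its own, and every test borrows its spread from the controls.

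Angiotensin II raised 9 of 21 growth factor and cytokine genes and 28 of 42 immediate early genes, and lowered TXNIP, GATA3 and CNR1 among others. The largest rise was that of INHBA, which encodes the subunit of activin A and was read on array B, from a control signal of 154.8 ± 72.1 (n = 2) to 10901, a log2 change of 6.07 ± 0.39 with an adjusted p of 2.82e-04. GEM, a small GTPase that restrains voltage-gated calcium channels, rose by 5.15 ± 0.14, the transcription factor FOSB by 5.08 ± 0.34 from a low control signal of 16.5, the orphan nuclear receptors NR4A2 by 4.82 ± 0.16 and NR4A3 by 4.11 ± 0.32, and the EGF-receptor ligand HBEGF by 4.74 ± 0.26. LIF, an interleukin-6 family cytokine, rose by 3.99 ± 0.29, TAC1, the precursor of substance P, by 3.77 ± 0.33, and the WNT inhibitor DKK1 by 3.73 ± 0.15. TXNIP, an inhibitor of thioredoxin and of glucose uptake, fell by 2.46 ± 0.16. The transcription factor GATA3 (−2.42 ± 0.17) and the cannabinoid receptor CNR1 (−2.34 ± 0.23) also fell.

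The other genes among the 15 largest rises were GCNA (4.30), PMEPA1 (4.0), MARCHF11 (3.64), the basement membrane protein NID1 (3.60), the interleukin-6 receptor IL6R (3.54) and the elongation factor ELL2 (3.36). The rise of PMEPA1 was 2.99 without control 1 and 5.0 without control 2, and that of IL6R 2.86 and 4.22. The other large falls were those of CCDC125 (−3.31), the mitochondrial prolyl-tRNA synthetase PARS2 (−3.17), PRDM16 (−2.97), CDK15 (−2.90), FAM81A (−2.86), PCDHB4 (−2.68) and DAPP1 (−2.43), all read on array B. The other 3 tested probe sets of DAPP1 gave −0.04, 0.33 and 0.37 and passed no test. Over the 155 probe sets called as at least 2-fold lower on array B, the 44 genes that array A also tested had a median of −0.22 there, against −1.40 on array B. In 6 of the 15 rises (FOSB, HBEGF, TAC1, MARCHF11, IL6R and ELL2) the control signal, and in 8 of the 10 falls (the 7 on array B and CNR1) the signal with angiotensin II, lay under the filter signal, so the sizes and ranks of these changes depend on the pseudocount. With a pseudocount of 1 or 64 in place of 16, FOSB gave 5.95 or 3.83, ELL2 4.32 or 2.19 and CCDC125 −4.03 or −2.27.

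**Figure D1:**
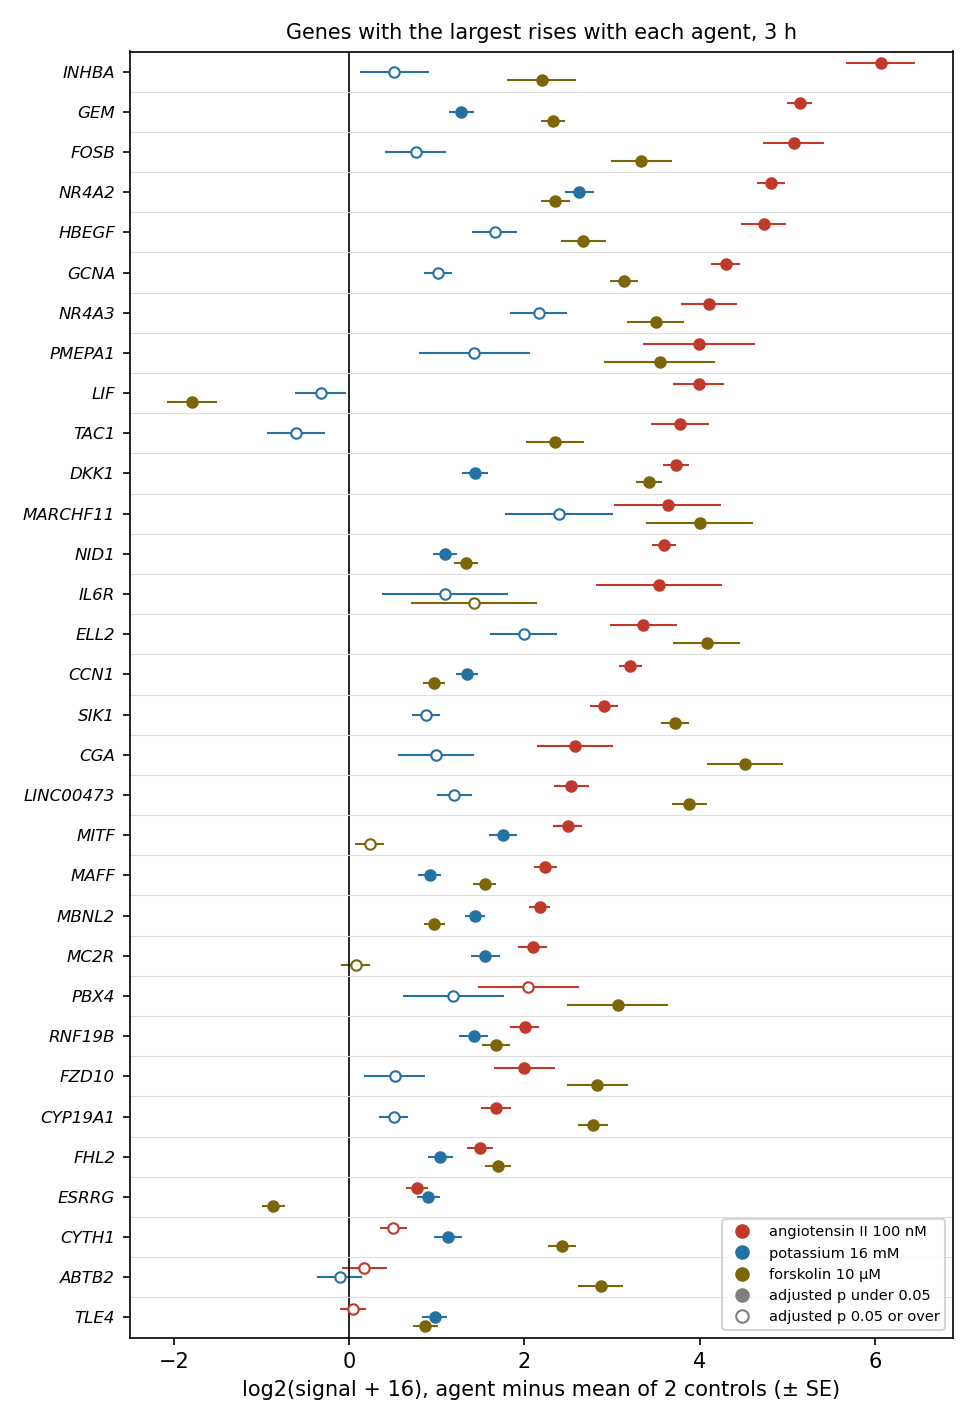
Genes among the 15 largest rises with any of the 3 agents, with the log2(signal + 16) of the agent's sample minus the mean of the 2 controls on the horizontal axis, 1 colour per agent. Filled points passed an adjusted p of 0.05 and bars are limma standard errors. INHBA lies at 6.07 with angiotensin II and CGA at 4.52 with forskolin, while LIF lies at 3.99 with angiotensin II and at −1.79 with forskolin.

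Of the steroidogenesis genes, 6 of the 20 tested rose with angiotensin II and 2 fell (7 and 4 adjusted over the list alone), and the list's median of 0.21 lay at percentile 99.9 of random lists. MC2R, the ACTH receptor, rose by 2.10 ± 0.17 from a control signal of 344.3 ± 38.0, with an adjusted p of 2.15e-04. FDX1, the electron donor of the mitochondrial P450 enzymes, rose by 1.05, the aromatase gene CYP19A1 by 1.68, and STAR, which carries cholesterol into mitochondria, by 0.64 ± 0.09 from 6442 ± 85.6 (adjusted p 0.00485). CYP11B1, the 11-beta-hydroxylase of cortisol synthesis, rose by 1.87 ± 0.30 from a low control signal of 75.9 ± 16.0, and SCARB1 by 0.50. HSD3B2 fell by 0.60 ± 0.11 and SULT2A1 by 0.60. The aldosterone synthase gene CYP11B2 gave 1.00 ± 0.34 with an adjusted p of 0.119, CYP17A1 gave 0.24 and CYP11A1 gave 0.26. None of them passed over all probe sets, and of them only CYP11B2 passed when adjusted over the list alone. AGTR1, the angiotensin type 1 receptor, fell by 1.25 ± 0.11 from 4214 ± 12.3, with an adjusted p of 2.98e-04. CYP11B1 and CYP11B2 are near-identical copies, so both values are uncertain. Without the filter the calls of STAR, CYP11B1 and HSD3B2 with angiotensin II were lost (adjusted p 0.0852, 0.109 and 0.0863), as they were without the trend on signal (adjusted p 0.144, 0.0521 and 0.153), and AGTR1 then had an adjusted p of 0.0553.

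Of 42 immediate early genes, 28 rose with angiotensin II and 2 fell (31 and 2 adjusted over the list alone), with a median of 1.31 at percentile 100. Besides GEM, NR4A2 and FOSB they included the matricellular gene CCN1 (3.21), MAFF (2.24) and TRIB1 (2.51), while BTG1 (−0.53) and IER5 (−0.68) fell. NR4A1 was read by 3 probe sets, all of which rose, by 1.35 (the one chosen by rule), 3.25 and 2.57. Of 33 cyclic AMP and CREB targets, 15 rose and 0 fell (17 and 0 adjusted over the list alone), with a median of 0.44 at percentile 100. They included STC1 (2.69) and the salt-inducible kinase SIK1 (2.91). Of 21 growth factor and cytokine genes, 9 rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 0.57 at percentile 100. TFPI2 (1.19), SOCS2 (1.40) and VEGFC (1.92) were among them.

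Among the 19 MAP kinase feedback regulators, 7 rose and 1 fell (8 and 2 adjusted over the list alone, median 0.18, percentile 99.7). SPRY2 rose by 2.18, RGS2 by 1.93 and the phosphatase DUSP1 by 2.02, whereas DUSP6, the phosphatase of ERK, fell by 2.12. Of 34 calcium and potassium handling genes, 5 rose and 3 fell (5 and 6 adjusted over the list alone, median 0.03, percentile 88.8). The transcription factor MEF2C (1.39) and the calcineurin regulator RCAN1 (1.19) rose, and the potassium channel KCNJ5 fell by 0.86. In the activin, inhibin, BMP and TGF-beta list, 2 of 23 rose and 4 fell (3 and 5 adjusted over the list alone, median 0.09, percentile 95.8). INHBA rose, and BMP4 (−1.84) and ID2 (−0.84) fell. Of 36 cell cycle genes, 2 rose and 11 fell (2 and 16 adjusted over the list alone), and the median of −0.27 lay at percentile 0. The inhibitor CDKN1A rose by 1.45, and the mitotic genes CDC20 (−1.37), CCNA2 (−0.78) and CENPA (−0.94) fell.

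Of 16 circadian genes, 3 rose and 2 fell (4 and 2 adjusted over the list alone, median 0.20, percentile 99.2), with NFIL3 up by 3.12 and BHLHE40 up by 2.17 and the clock output gene DBP down (−1.31). Of 28 genes of unfolded protein and amino acid stress, 3 rose and 0 fell (4 and 0 adjusted over the list alone, median 0.04, percentile 96.2), led by PPP1R15A (1.46). Of 27 glycolysis and hypoxia genes, 4 rose and 0 fell, also adjusted over the list alone (median 0.12, percentile 99.1), namely PFKP (0.79), VEGFA (0.67), PFKFB3 (1.06) and P4HA1 (0.90). Of 13 heat shock genes, 2 rose and 0 fell, also adjusted over the list alone. Their median of 0.18 (percentile 99.5) changed sign to −0.01 with quantile normalization. Of 28 cholesterol genes, 0 rose and 1 fell (1 and 5 adjusted over the list alone, median −0.09, percentile 28.8). That gene was SC5D (−0.52).

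With angiotensin II, 733 probe sets were higher and 705 lower than in the controls by limma, 1438 of 26875 tested, of which 970 were on array A and 468 on array B. Counting each gene once, 385 genes rose and 435 fell. By size alone, 2049 probe sets were at least 2-fold from the control mean, against 1269 with the controls 2-fold apart, and on array A 523 against 118. The count depends on the variance model and the filter, as it was 334 without the filter and 160 without the trend on signal, with 74.6% and 78.8% of these higher in place of 51.0%, 230 with the prior degrees of freedom halved and 244 when tested against a minimum fold of 1.5. Of the 25 named genes, 12 kept their call in all 8 alternatives of scaling, pseudocount, filter and variance model that measured them (GEM, FOSB, NR4A2, HBEGF, NR4A3, LIF, TAC1, DKK1, NID1, TXNIP, GATA3 and CNR1).

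Forskolin raised 17 of 33 cyclic AMP and CREB targets and, of the cortisol pathway, STAR, CYP11A1, CYP17A1 and CYP11B1, while HSD3B2 fell. CGA, the alpha subunit of the glycoprotein hormones, rose by 4.52 ± 0.43 on array A, from a control signal of 35.2 ± 25.8 (n = 2) to 1077, with an adjusted p of 7.30e-04. ELL2 rose by 4.08 ± 0.38 from a low control signal of 14.5, the long non-coding RNA LINC00473 by 3.88 ± 0.20, SIK1 by 3.72 ± 0.16, NR4A3 by 3.50 ± 0.32, DKK1 by 3.42 ± 0.15 and FOSB by 3.34 ± 0.34. CYP19A1 rose by 2.78 ± 0.17 and the WNT receptor FZD10 by 2.83 ± 0.35. TXNIP fell by 2.00 ± 0.16, OAS1, an interferon-induced antiviral enzyme, by 2.12 ± 0.17, and TRIB2 by 2.05 ± 0.12.

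The other large rises with forskolin were those of MARCHF11 (4.0), PMEPA1 (3.54), GCNA (3.14), PBX4 (3.07), ABTB2 (2.88) and HBEGF (2.68). PMEPA1 gave 2.54 without control 1 and 4.55 without control 2. The other large falls were those of the antisense transcript TRG-AS1 (−4.45), the LIM homeobox gene LHX4 (−3.07), NFATC2 (−2.68), KLK7 (−2.66), GKN2 (−2.45) and TRIM52-AS1 (−2.43), all read on array B, and of PECR (−1.95). In 7 of the 15 rises (CGA, ELL2, MARCHF11, FOSB, PBX4, FZD10 and HBEGF) the control signal, and in 7 of the 10 falls (the 6 on array B and PECR) the signal with forskolin, lay under the filter signal. With a pseudocount of 1 or 64, CGA gave 5.11 or 3.55, ELL2 5.08 or 2.83 and TRG-AS1 −5.21 or −3.32.

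Of the 20 steroidogenesis genes, 7 rose with forskolin and 1 fell (8 and 3 adjusted over the list alone), with a median of 0.34 at percentile 100. STAR rose by 0.95 ± 0.09 (adjusted p 7.45e-04), FDX1 by 0.92, CYP17A1, the 17-alpha-hydroxylase, by 0.98 ± 0.12 (adjusted p 0.00344), CYP11B1 by 2.10 ± 0.30, POR by 0.97 and CYP11A1, the cholesterol side-chain cleavage enzyme, by 0.52 ± 0.10. HSD3B2, which encodes the 3-beta-hydroxysteroid dehydrogenase of the adrenal, fell by 1.03 ± 0.11 from 4165 ± 90.5, with an adjusted p of 0.00118. CYP11B2 gave 0.77 ± 0.34 with an adjusted p of 0.271. MC2R gave 0.08 ± 0.17 with an adjusted p of 0.865. AGTR1 fell by 0.84 ± 0.11. The call of CYP11A1 was lost with quantile normalization (0.44, adjusted p 0.0751), and without the filter those of CYP11A1 (adjusted p 0.152), CYP17A1 (adjusted p 0.0588), CYP11B1 (adjusted p 0.117) and AGTR1 (adjusted p 0.0549) were lost. Without the trend all of these and those of STAR and HSD3B2 were lost, with adjusted p-values of 0.228 for CYP11A1, 0.13 for CYP17A1, 0.0633 for CYP11B1, 0.146 for AGTR1, 0.127 for STAR and 0.113 for HSD3B2.

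**Figure D2:**
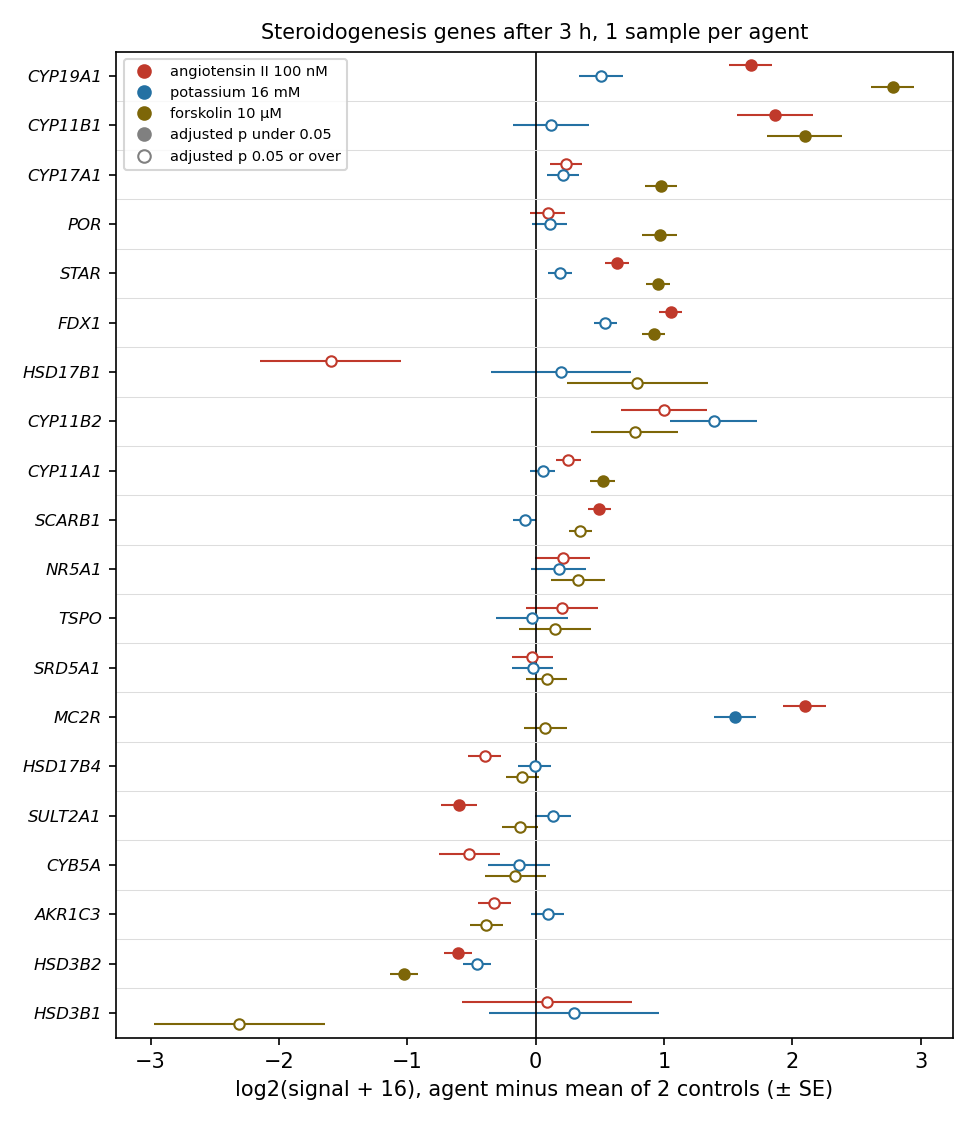
The 20 tested steroidogenesis genes, with the log2(signal + 16) of the agent's sample minus the mean of the 2 controls on the horizontal axis, 1 colour per agent, filled where the adjusted p was under 0.05, with limma standard errors as bars. MC2R lies at 2.10 with angiotensin II, 1.56 with potassium and 0.08 with forskolin, and HSD3B2 lies below 0 with each agent, open for potassium.

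Of the 33 cyclic AMP and CREB targets, 17 rose and 0 fell (19 and 1 adjusted over the list alone), with a median of 0.63 at percentile 100. After SIK1 the smallest adjusted p-values were those of CREM (1.81), GEM (2.33) and STC1 (2.24), and the phosphodiesterase genes PDE7B (1.48), PDE4D (1.08), PDE8A (0.62) and PDE4B (1.14) were also among them. Of 42 immediate early genes, 23 rose and 1 fell (26 and 2 adjusted over the list alone), with a median of 0.80 at percentile 100. RHOB rose by 1.65 and NR4A2 by 2.35, and BTG1 fell by 0.80. NR4A1 gave 0.73 with an adjusted p of 0.135 on its chosen probe set, 2.58 (adjusted p 1.49e-04) and 0.35 (adjusted p 0.427) on the others, whose probes can also match other transcripts. For NR4A3 the probe sets other than the chosen one gave 3.71, which passed, and 0.77, which did not. Of 21 growth factor and cytokine genes, 6 rose and 1 fell (7 and 2 adjusted over the list alone, median 0.30, percentile 100). FGF9 rose by 1.96, and LIF fell by 1.79. In the activin, inhibin, BMP and TGF-beta list, 3 of 23 rose and 1 fell (6 and 1 adjusted over the list alone, median 0.23, percentile 99.96). BMP4 fell by 0.94, and INHBA (2.20), INHA (1.06) and FST (0.92) rose.

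Of 19 MAP kinase feedback regulators, 4 rose and 5 fell with forskolin (5 and 6 adjusted over the list alone, median −0.11, percentile 18.2), with SPRY2 (1.75), DUSP1 (1.60) and DUSP16 (1.71) up and DUSP6 (−1.37) down. Of 34 calcium and potassium handling genes, 2 rose and 5 fell (2 and 7 adjusted over the list alone, median −0.04, percentile 59.1). ATP1B3 rose by 1.92 and the inositol trisphosphate receptor ITPR1 by 2.01. Of 36 cell cycle genes, 0 rose and 4 fell (1 and 12 adjusted over the list alone, median −0.29, percentile 0), and these were CDC20 (−1.38), PLK1 (−0.74), BUB1 (−0.70) and CENPA (−0.71). Of 28 cholesterol genes, 2 rose and 0 fell, also adjusted over the list alone (median 0.19, percentile 100), namely NSDHL (0.98) and SOAT1 (1.08). The counts were 2 up and 1 down of 28 for unfolded protein and amino acid stress (5 and 1 adjusted over the list alone, median 0.19, percentile 100), 3 up and 0 down of 27 for glycolysis and hypoxia (4 and 0 adjusted over the list alone, median 0.10, percentile 99.2), led by NDRG1 (1.5), 1 up and 1 down of 16 for the circadian clock (1 and 2 adjusted over the list alone, median 0.02, percentile 85.4) and 0 of 13 for heat shock (0 adjusted over the list alone, median 0.05, percentile 83.1).

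By limma 534 probe sets were higher and 312 lower with forskolin, 846 in all, 604 on array A and 242 on array B. Of these calls 63.1% were rises, against 75.2% after centring on the array medians. Counting each gene once, 292 genes rose and 189 fell. By size alone 1480 probe sets were at least 2-fold from the control mean, and 358 on array A. The count was 210 without the filter, 123 with the prior degrees of freedom halved, 168 against a minimum fold of 1.5, and 0 without the trend on signal, where none of the 25 named genes kept its call. Without the filter 12 of them did, ELL2, LINC00473, SIK1, DKK1, GCNA, ABTB2, CYP19A1, TRG-AS1, TRIM52-AS1, OAS1, TRIB2 and TXNIP.

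Potassium raised 14 genes past the test and lowered 1. NR4A2 rose by 2.63 ± 0.16 on array A, from a control signal of 123.2 ± 10.3 (n = 2) to 843.4, with an adjusted p of 5.75e-04. The transcription factor MITF rose by 1.75 ± 0.16, the ACTH receptor MC2R by 1.56 ± 0.17 (adjusted p 0.0129), the splicing regulator MBNL2 by 1.44 ± 0.12 and DKK1 by 1.44 ± 0.15. CCN1 rose by 1.34 ± 0.13 and GEM by 1.28 ± 0.14. TXNIP fell by 1.39 ± 0.16, with an adjusted p of 0.0151.

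The remaining genes that rose were RNF19B (1.42), CYTH1 (1.13), NID1 (1.10), FHL2 (1.04), TLE4 (0.98), MAFF (0.92) and the orphan nuclear receptor ESRRG (0.91). NR4A3 gave 2.16 ± 0.32 with an adjusted p of 0.0536 on its chosen probe set, and 2.20 with an adjusted p of 5.75e-04 on another. Its remaining tested probe set gave 0.18 and did not pass. NR4A1 gave 0.43 on its chosen probe set (adjusted p 0.735), and its other probe sets gave 1.38 (adjusted p 0.0279) and −0.07. CYP11B2 gave 1.39 ± 0.34 with an adjusted p of 0.259, from control signals of 153.4 and 82.1 to 321.2. STAR (0.19), CYP11B1 (0.12), CYP17A1 (0.22), CYP11A1 (0.06), HSD3B2 (−0.45) and AGTR1 (−0.21) did not pass over all probe sets. Adjusted over the steroidogenesis list alone, CYP11B2 and HSD3B2 passed, and STAR, CYP11B1, CYP17A1 and CYP11A1 did not.

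Of the lists, 4 of 42 immediate early genes rose and 0 fell (10 and 1 adjusted over the list alone), with a median of 0.17 at percentile 100. In the cyclic AMP and CREB list, 2 of 33 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 0.44 at percentile 100. Both of these 2 are among the 4 immediate early genes already counted. In the steroidogenesis list MC2R rose and none of the 20 fell (3 and 1 adjusted over the list alone), with a median of 0.13 at percentile 99.7. No other list had a member past the test over all probe sets. Adjusted over the list alone, 4 of 19 MAP kinase feedback regulators rose (median 0.09, percentile 96.7), 2 of 21 growth factor and cytokine genes (median 0.11, percentile 99.2), 2 of 16 circadian genes (median 0.12, percentile 98), 1 of 34 calcium and potassium handling genes (median 0.05, percentile 94.6), and 1 of 28 genes of unfolded protein and amino acid stress while 1 fell (median 0.02, percentile 78.7). Adjusted in the same way, 0 genes passed in the lists for cholesterol (median −0.06, percentile 12.2), the activin group (median 0.00, percentile 77.9), the cell cycle (median −0.00, percentile 50.6), heat shock (median 0.02, percentile 64.3) and glycolysis and hypoxia (median −0.00, percentile 60.6).

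**Figure D3:**
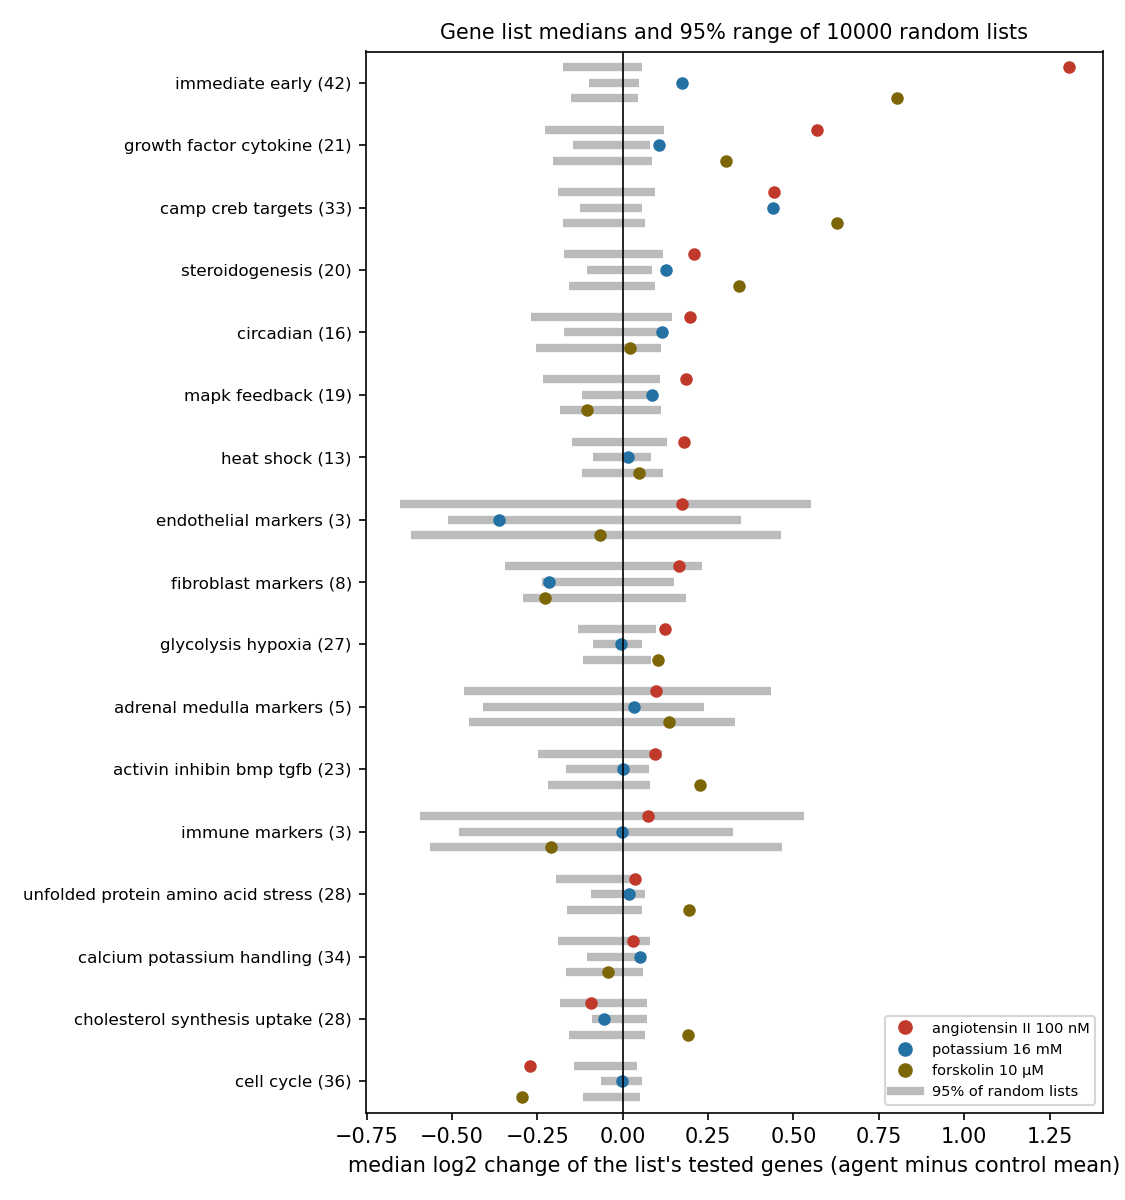
Median log2 change of each gene list's tested genes, numbers of genes in parentheses, for each agent against the control mean, with the central 95% of 10000 random lists matched on signal as grey bars. The immediate early list lies at 1.31 with angiotensin II, 0.80 with forskolin and 0.17 with potassium, and the cell cycle list at −0.27, −0.29 and −0.00.

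With potassium, 26 probe sets were higher and 2 lower by limma, 28 in all, of which 27 were on array A. False calls may be as many, since 10 simulated draws with 200 changed probe sets each gave 341 false calls on array A. At an unadjusted p under 0.05 there were 1865, and 847 probe sets were at least 2-fold from the control mean. Against control 2 alone this count was 1131 and against control 1 alone 1321, on either side of the 1269 between the controls. The calls depend on the processing, as 11 probe sets passed with quantile normalization, 75 with the lowest 60% left out, 4 against a minimum fold of 1.5, and 0 without the filter, without the trend or with the prior degrees of freedom halved. Of the 15 named genes, quantile normalization kept the calls of NR4A2 and MBNL2 alone, with MC2R at 1.57 and an adjusted p of 0.0813.

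LIF was higher with angiotensin II than with forskolin by 5.78 ± 0.33 (adjusted p 4.90e-04), a size that depends on the pseudocount (6.55 with 1, 4.59 with 64) because its signal with forskolin was 19.9, and than with potassium by 4.31 ± 0.33. INHBA was higher with angiotensin II than with forskolin and potassium by 3.87 ± 0.46 and 5.55 ± 0.46. MC2R was higher than with forskolin both with angiotensin II (by 2.02 ± 0.19, adjusted p 0.00174) and with potassium (by 1.48 ± 0.19, adjusted p 0.00857). CYP17A1 was lower than with forskolin both with angiotensin II (−0.74, adjusted p 0.0349) and with potassium (−0.76, adjusted p 0.0446). CYP11B1 was lower with potassium than with forskolin (−1.98, adjusted p 0.0306) and higher with angiotensin II than with potassium by 1.75 (adjusted p 0.0343). For CYP11B2 no difference between agents passed, with adjusted p-values of 0.648, 0.833 and 0.597.

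Between angiotensin II and potassium, the largest differences upward after INHBA were those of TAC1 (4.38), FOSB (4.32), LIF and GEM (3.86), and those downward were USP20 (−2.74), CDK15 (−2.35), FANCF (−2.30), TRAPPC12 (−2.23) and DUSP6 (−2.04). Between angiotensin II and forskolin, LHX4 (3.45), NFATC2 (3.40) and LYVE1 (3.20), a hyaluronan receptor, followed LIF and INHBA, and ABTB2 (−2.70), MIB2 (−2.66), ADAMTS6 (−2.46), USP20 (−2.34) and CNR1 (−2.28) were lower with angiotensin II. Between potassium and forskolin, TRG-AS1 (3.64), MYB (1.84), ESRRG (1.77), ARID5B (1.68) and MITF (1.52) were higher with potassium, and CGA (−3.53), ABTB2 (−2.98), TAC1 (−2.96), SIK1 (−2.84) and LINC00473 (−2.68) were lower. The lower of the signals compared lay under the filter signal for 7, 6 and 3 of the 10 genes of each difference, among them TAC1, FOSB, LIF, USP20, FANCF, LHX4, NFATC2, TRG-AS1 and CGA, whose sizes also depend on the pseudocount.

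In all, 313 probe sets were higher and 166 lower with angiotensin II than with potassium, 289 higher and 240 lower with angiotensin II than with forskolin, and 64 higher and 164 lower with potassium than with forskolin, by limma. After centring on the array medians the share of differences upward was 52.7% in place of 65.3% between angiotensin II and potassium, and 34.1% in place of 54.6% between angiotensin II and forskolin. The counts of 479, 529 and 228 fell to 20, 1 and 0 without the filter and to 0 each without the trend or with the prior degrees of freedom halved, and each compares 1 sample with 1 sample.

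Angiotensin II and forskolin changed many of the same genes. Counting each gene once, 146 genes rose with both and 71 fell with both, where independent lists would share 9.09 and 6.65. They included SIK1, STC1, DUSP1 and NR4A3 among the rises and TXNIP, DUSP6 and CDC20 among the falls. The 9 genes changed in opposite directions were LIF, ESRRG, KCNK1, RGL1, FBXW7, STK38L, TNS3 and ZBTB20, which rose with angiotensin II and fell with forskolin, and ARMCX6, which did the reverse. Genes changed by all 3 agents were NR4A2, GEM, DKK1, NID1, CCN1, MAFF, MBNL2, RNF19B and FHL2, which rose, and TXNIP, which fell.

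By probe sets, angiotensin II and forskolin shared 274 rises and 113 falls (independent lists 14.6 and 8.18, simulated unchanged agents 0.04 and 0.16) and 16 went opposite ways. Angiotensin II and potassium shared 24 rises and 2 falls (independent lists 0.709 and 0.0525, simulated 0.14 and 0.18). Potassium and forskolin shared 21 and 2 (independent lists 0.517 and 0.0232, simulated 0.12 and 0.12). Across probe sets, which are not independent replicates, the log2 changes correlated with r = 0.451 for angiotensin II and forskolin, 0.369 for angiotensin II and potassium and 0.416 for potassium and forskolin, against 0.335, 0.334 and 0.335 in simulations of unchanged agents with the same controls. The covariances exceeded the simulated ones by 0.0919, 0.0459 and 0.0445. With a different control for each agent, r was 0.222 and 0.229, 0.113 and 0.110, and 0.113 and 0.126. Part of the overlaps, of probe sets and of genes, may come from the shared controls, which the numbers for independent lists leave out. Those numbers also ignore that calls gathered among bright probe sets. On array B, angiotensin II and forskolin had 358 and 197 calls in the brightest class of signal, and 23 and 10 in the dimmest. Unchanged agents give few calls, so their simulated overlap is small in advance and does not measure what shared controls add. The 387 shared calls of angiotensin II and forskolin were 108 without the filter and 0 without the trend.

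Taking the 3 agents as replicates of stimulation, 0 probe sets differed between the 3 stimulated and the 2 control samples by limma, with a smallest adjusted p of 0.184, and 2108 had an unadjusted p under 0.05. For example HSD3B2 gave a mean change of −0.70 and STAR one of 0.59, neither past the adjusted threshold. Without the potassium sample 182 probe sets passed, without angiotensin II 3, without forskolin 1 and without either control 0.

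The same RNA on array B gave a check of the array A calls. Of 191 genes called with angiotensin II on array A that also had a tested probe set on array B, 158 (82.7%) had the same sign there. With forskolin 118 of 139 (84.9%) did, and with potassium 3 of 3. Of all 2333 genes tested on both, 62.4%, 60.2% and 56.5% had the same sign with angiotensin II, forskolin and potassium. Fewer were also called on array B, 46 of the 191, 40 of the 139 and 1 of the 3. For the 100 probe sets present on both array types, the log2 changes on A and B differed with an SD of 0.232, 0.190 and 0.176 for angiotensin II, potassium and forskolin, by a mean of −0.03, −0.02 and −0.14 (A minus B). Across these probe sets they correlated with r = 0.382, −0.0626 and 0.416. With angiotensin II 2 of them were called on A and 2 on B, with forskolin 1 and 1, with potassium 0 and 0, and none on both. With so few calls among them, these correlations say little about genes that changed. Their SD does not stand for array B at large, where the log2 difference of the 2 controls had an SD of 0.586. The offset of −0.14 with forskolin is larger in size than some list medians, such as 0.10 for glycolysis and hypoxia. Its cause was not tested. Of genes with several tested probe sets, 630, 15 and 365 were called with angiotensin II, potassium and forskolin. At least 2 probe sets were called in 189, 6 and 135 of them, and 0 genes were called in both directions.

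Markers of other cell types did not move past the test with any agent, also adjusted over the list alone, though few were bright enough to test. These were 5 genes of the adrenal medulla, 3 of endothelium, 8 of fibroblasts and 3 of immune cells. With angiotensin II their medians lay at percentiles 64.4, 76.3, 93.7 and 60.5 of random lists, with potassium at 78.3, 9.37, 4.13 and 65.0, and with forskolin at 84.8, 51.1, 7.79 and 26.0. The brightest were SPARC at a control signal of 7036, FLT1 at 737.8 and FAP at 710.1, with log2 changes with angiotensin II of 0.03, −0.19 and 0.24. The ratio of 3′ to 5′ GAPDH signal on array A, a measure of RNA integrity, was 0.783 and 0.814 in the controls, 0.755 with angiotensin II, 0.800 with potassium and 0.785 with forskolin. On array B it was 1.04 and 0.980 in the controls, 0.953 with angiotensin II, 0.970 with potassium and 1.07 with forskolin, the last above both controls.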

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

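The count in this part was defined after the calls had been seen, and its size was compared with a similar count in each control. For an agent, both controls had to lie under the filter signal, and for a control only the other control. The control counts follow this looser rule and are not fully alike. Probe sets left out of the tests because their mean signal was low can still be bright in 1 sample. With angiotensin II, 112 such probe sets reached at least 2 times the filter signal of their array type, 11 on array A and 101 on array B. The number was 22 with potassium and 38 with forskolin, and by the looser rule 80 in control 1 and 35 in control 2. On array B control 1 had 79 and control 2 had 34. The unlike rules leave open how far the 101 with angiotensin II stands above the controls. On array A, where each control had 1, the 11 with angiotensin II and the 8 with forskolin stand further apart. They include a probe set of INHBA on array A, at 8.6 and 8.2 in the controls and 2263 with angiotensin II. No explanation was tested for this count.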

How the results depend on the processing

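Array A alone, the overlap with a different control for each agent and the halved prior degrees of freedom were chosen after seeing the data, and the other alternatives were planned. No paired analysis was possible because only the controls carry replicate numbers and each agent has 1 sample. The limits are the 1 residual degree of freedom, the lone agent samples and the noise of array B, whose dimmer probe sets give few calls. No value of the 95 named genes and differences changed sign under any alternative that measured it. For most alternatives this was fixed in advance. Named genes had to change in the same direction against each control, so another pseudocount or a left-out control could not reverse them. Filters and variance models leave the size of a change as it is. Only the scalings could have reversed a sign. Without control 1, and likewise without control 2, 6 of the 95 values moved by more than their limma standard error. These were INHBA, NR4A3 and PMEPA1 with angiotensin II and CGA, NR4A3 and PMEPA1 with forskolin. The differences between agents among the 95 contain no control, so they could not move here. Centring on the array median kept the calls of all 95, robust eBayes 94 of 95, a pseudocount of 64 kept 93, a pseudocount of 1 kept 87 of 90, quantile normalization 78, no filter 29, and eBayes without the trend 13. All 56 measured with the lowest 60% left out kept theirs. Of the list genes called, 33 of 102 with angiotensin II kept their call in all of these 8 alternatives that measured them. With the lowest 60% left out, 86 of the 102 were measured. With forskolin 58 of 82 kept theirs with quantile normalization, 27 without the filter and 0 without the trend. The median of all changes moved by less than 0.1 under each scaling.

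With quantile normalization potassium changed 11 probe sets (28 as reported, 6 of them shared), and the heat shock median with angiotensin II turned to −0.01 (−0.012). The cause was not tested. No other list median outside the random range changed sign. With a pseudocount of 64 the counts at least 2-fold from control were 503 for potassium and 963 for forskolin, as a larger pseudocount shrinks dim changes. Without the filter angiotensin II changed 334 probe sets, potassium 0 and forskolin 210, the differences were 20 (angiotensin II and potassium), 1 (angiotensin II and forskolin) and 0 (potassium and forskolin), the counts at least 2-fold from control were 5607, 3755 and 4758, and angiotensin II and forskolin shared 108. With the lowest 60% left out potassium changed 75, the differences were 801 (angiotensin II and potassium) and 390 (potassium and forskolin), and the 2-fold counts were 869, 178 and 581, with fewer probe sets tested. In eBayes without the trend angiotensin II changed 160, potassium 0 and forskolin 0, the differences were 0, 0 and 0 and the shared calls 0. With the prior degrees of freedom halved the changes were 230, 0 and 123 and the differences 0, 0 and 0, because fewer degrees of freedom widen every interval. Against a minimum fold of 1.5 (treat) the changes were 244, 4 and 168. On array A only, the 2-fold counts were 523, 97 and 358.

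Leaving out a control leaves the agent tests without a residual degree of freedom, so they have no value then. The 2-fold count of potassium ranged from 1131 to 1321 without a control (847 as reported), that of angiotensin II from 2342 to 2497 and that of forskolin from 1804 to 1935. The stimulated samples against controls gave 0 to 182 probe sets when a sample was left out, with 182 without potassium. The number of list medians outside the central 95% of random lists was 23 as reported and 21 to 27 under the alternatives.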

Other observations

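The tests of RNA degradation, of a lone culture and of a noisier potassium array were chosen after the result was seen, and the lists of interferon-response and WNT genes and of gene families were made after the calls had been seen. Genes of WNT signalling moved in both directions. With angiotensin II, 3 of 42 tested rose and 6 fell. The secreted inhibitors DKK1 (3.73) and SFRP1 (1.56) and the receptor FZD10 (2.00) rose, and the receptors FZD2 (−1.05) and FZD7 (−0.84), the ubiquitin ligase RNF43 (−0.99), the feedback gene AXIN2 (−0.97), the transcription factor LEF1 (−0.77) and APC (−0.63) fell. With forskolin 5 rose and 2 fell, among them SFRP1 (2.16) and FZD4 (2.11) up and FZD7 (−1.18) and LEF1 (−0.74) down. Of the 36 members not seen among the calls when the list was made, 0 rose and 5 fell with angiotensin II. With forskolin 0 of them rose and 1 fell. All members that rose with either agent had been seen, so the absence of rises here follows from taking them out.

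Of 47 interferon-response genes tested, 0 rose and 4 fell with angiotensin II, namely IFIT1 (−2.04), OAS1 (−1.97), SAMD9 (−1.29) and IFI16 (−0.93). With forskolin 5 fell, OAS1 (−2.12) and IFI16 (−1.18) among them. All of these were among the 7 members already seen among the calls when the list was made. Of the 40 others 0 fell with either agent, which follows from taking out the called members. Of 346 zinc finger genes whose symbols begin with ZNF, 7 rose and 11 fell with angiotensin II, but the median was −0.24, at percentile 0 of random lists matched on signal, and −0.24 with quantile normalization and −0.28 after median centring. The median was −0.13 with forskolin (−0.09 and −0.05 with those scalings) and −0.08 with potassium (−0.04 and −0.02). Of 12 KLF transcription factor genes, 2 rose with angiotensin II and the median was 0.63 (0.67 and 0.62 with those scalings), and 0.25 with forskolin. KLF2, KLF4, KLF6, KLF9 and KLF10 are also members of the immediate early list. The 2 that rose with angiotensin II, KLF6 and KLF10, are already counted there, so the family partly repeats that result. The 27 genes of the small mitochondrial ribosomal subunit had a median of −0.27 with angiotensin II (percentile 0.36), with 0 past the test, and −0.24 and −0.28 under those scalings. It was −0.11 with potassium (percentile 0.36, and −0.13 and −0.05 under those scalings) and −0.17 with forskolin (percentile 1.27, and −0.16 and −0.12), against the same 2 controls. The 49 genes of the large subunit had a median of −0.15 with angiotensin II, at percentile 6.11 and so inside the random range.

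Angiotensin II gave more calls than the other agents. A fault of the array A hybridisation would leave the same RNA on array B without the change. However, 82.7% of the array A calls had the same sign there, against 62.4% of all genes tested on both. Of these 191 array A calls, 46 were also called on array B. Degraded RNA would raise the 3′ to 5′ ratio of GAPDH, which was 0.755 on array A and 0.953 on array B, below both controls on each. A difference that arose before hybridisation would show on both array types, so the comparison of arrays cannot exclude it. A culture that differed for reasons other than the agent also stays open, since there is 1 angiotensin II culture. Neither can be told apart from an effect of angiotensin II.

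Falls of at least 2-fold called on array B with angiotensin II (155 probe sets) included most of the largest named falls. For 44 of their genes array A also had tested probe sets, and these had a median of −0.22 (95% bootstrap interval −0.53 to −0.09), against −1.40 on array B. For 46 genes with such rises the median was 1.08 on array A and 1.58 on array B. Noise of lone array B probe sets (median −0.2175) and a true fall of these transcripts (upper bound −0.0895) cannot be told apart by the limit of −0.3 set for the test, since the interval spans it. In 36 of the 44 genes the array A change was also negative, so a mixture of real falls and probe sets picked for their noise may be at work.

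Potassium gave few calls. A noisier potassium array would widen the changes of probe sets that no agent changed, but their SD on array A was 0.257 with potassium, against 0.325 with angiotensin II, 0.305 with forskolin and 0.259 from the spread of the controls. The 274 probe sets raised by both other agents had a median potassium change of 0.44, and 92.0% were above 0, whereas simulations without a potassium effect gave medians of −0.02 to 0.05. The median of these 274 probe sets was 1.40 with angiotensin II and 1.32 with forskolin. The simulations took the observed control means as true. They therefore leave out the selection of probe sets whose controls, shared by all agents, read low. How much of the 0.44 and the 92.0% comes from that selection cannot be told. A hypothesis consistent with these values is that potassium moved the same genes by a smaller amount, most of it below what 1 sample can show by the test. Dose and time were not varied, so a slower or a weaker stimulus remains untested.

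The hypothesis that interferon-response genes fell as a group remains open. The 40 members not seen among the calls had a median at percentile 4.38 of random lists with angiotensin II and at 2.20 with forskolin, where the limit set for the test was 2.5 and the number of random lists gives an error of 0.312, while all 47 members lay at 0.01 and 1.43. With potassium all 47 lay at 1.01, and since the agents share both controls, high values in the controls could produce the same pattern. The 40 were left after called members were taken out, while the random lists kept their called genes. The percentiles of the 40 therefore lean toward no fall. The hypothesis that WNT pathway genes rose as a group with forskolin was not borne out. The members not seen among the calls lay at percentile 25.96 and all 42 at 71.4. Taking out called members also pulls the 25.96 toward no rise, but the 71.4 includes them.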
